A study of Mus musculus with 6 samples.

How the data were processed

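RNA from whole mammary glands of 3 wild-type and 3 Elf5 knockout (KO) mice was measured on 6 one-colour Affymetrix mouse expression arrays, 1 array per sample. Groups and replicate numbers 1 to 3 came from the sample titles, which speak of animals and biological replicates. The sample labels place the glands at pregnancy day 17, whereas the series' design text speaks of lactation day 1. Both describe the same 6 arrays, and the stage is left open here.

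The deposited table holds linear signal intensities for 45101 probe sets. The authors made them with MAS5 and the affy package, per the submitters' processing notes, which give no version, role or order. The values show that each array was scaled: the mean after trimming 2% at each end was 150 in every array. Column medians were 41.3, 38.8 and 34.3 in wild type and 36.1, 31.6 and 24.6 in the KO. Array image files and detection calls were not used here, and a build or genome coordinates are not given in the sources used here. For arrays, the number of arrays limits the precision.

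Probe sets were named through the platform's gene annotation. Of all probe sets, 34945 had 1 gene, 932 had several and 9211 were not listed, and no gene was named from the last 2 kinds. Symbols were checked against a current gene table through Entrez numbers; 0 probe sets needed an update and 204 had no current entry. Of 18193 genes with a probe set, 9010 had several, and the one with the highest mean over the 6 arrays stood for the gene. The 64 control probe sets were left out of the gene tests.

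Signals were tested as log2(signal + 16), so fold changes are on that scale and understate the change of dim genes. Genes with a mean under the 40th percentile were left out, which left out 7277, below a signal of about 43.8, and kept 10916. The deposited scaling was kept. The 2 groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), without a block, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Errors of differences are limma's moderated standard errors (SE) with n = 3 arrays per group. Adjusted p-values below come from this fit unless another is named.

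A total of 30 gene lists was written before the data were examined, among them markers of the other cell types of a whole gland. The 28 lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, which compares a list with the other genes. Camera with an estimated correlation and fry, whose p asks whether a list's genes move on balance in one direction, were run beside it. The 2 lists with fewer members, erythroid cells and skin keratinocytes, were not tested. Counts of list members are over all genes tested, or "adjusted over the list alone" where said.

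Named genes followed a rule written before the data were examined. It took Elf5, the 8 largest rises and 8 largest falls among called genes whose groups did not overlap (passing over clone names), the 3 members of each list with the smallest p, and Snai2, Stat5a, Stat5b, Csn2, Wap, Lalba, Krt5, Krt8, Krt14 and Notch1. Other genes are named only where said. Of 29 called genes among these, 8 had several probe sets, and for Igfbp5, Fn1 and Cldn1 another probe set had the opposite sign. Some list members were not analysed here.

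Whether replicate numbers pair the animals is not stated in the labels. Arrays with the same number deviated together from their group means: the correlations across genes were 0.46, 0.34 and 0.29 for numbers 1, 2 and 3, and the highest between different numbers was 0.15. All 6 arrays correlated best with their own number. With 3 arrays per group few matchings are possible, so chance alone can give this one. Dap and Thr, poly-A controls added to the RNA, followed the number too. Dap read 2414, 128 and 983 in wild-type arrays 1, 2 and 3, and 1341, 93.7 and 567 in the KO. Thr read 455, 25.2 and 127 in wild type, and 257, 2.9 and 96.2 in the KO. These controls do not come from the animals, so arrays of the same number may have been handled together, which the labels do not state. Neither match shows that the animals were paired. Each of the 3 correlations was over 0.1, the limit set beforehand, so a fit with the replicate number as a block ("paired fit") is given where it changes a call or moves a count by over 1.5 times. The number of calls with the block had already been seen when these correlations were computed.

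Control ratios between groups were tested with a two-sided exact permutation test, for which 3 against 3 arrays give no p under 0.1. The fits were tested on simulated data. On 10916 simulated genes with independent arrays and the measured spread, the unpaired fit recovered 58% of 100 genes changed by 2 on the log2 scale and 5% of 100 changed by 1, with 10 false calls, and the paired fit 0% of both. With a shared effect of each replicate number, the paired fit recovered 78% and 8%, with 2 false calls. The unpaired fit recovered 42% and 0% there, with 0 false calls. That shared effect was set stronger than the measured correlations between arrays of the same number. These figures therefore do not show how much the paired fit gains on the measured arrays. A cholesterol list lowered by 1 in simulated data was found by camera (adjusted p = 1.23e-13), and 1 other list of 28 passed as well. Each simulated gene varied on its own, with no correlation between list members. The estimated correlation was 0.20 within the measured cholesterol list and 0.85 within milk proteins. The simulation therefore does not show how camera behaves on correlated lists.

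Alternatives set before the data were examined were pseudocounts of 1 and 64, no filter on dim genes or one at the 60th percentile, quantile normalization, median centring, eBayes without trend or robust, array weights, the mean of a gene's probe sets, leaving out probe sets ending in _s_at or _x_at, testing all probe sets, the replicate block, leaving out each array, other list tests, camera on ranks, a threshold of 0.1, and treat against a fold of 1.5. Added after the control ratios had been seen were the 4 arrays with a Gapdh ratio under 2, the log2 Gapdh ratio as a covariate, and the paired fit on 2 replicate numbers at a time. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.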

Results

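Gene expression was measured in whole mammary glands of 3 wild-type and 3 Elf5 KO mice. Elf5 encodes an ETS transcription factor of the luminal epithelium. The sample labels give pregnancy day 17 and the series' design text lactation day 1, so the glands are described here without a stage. The comparison asks which transcripts differ in the gland when Elf5 is disrupted. Over the genes tested, correlations between arrays were 0.82 to 0.95 within groups and 0.72 to 0.92 between groups. KO array 1 correlated with wild-type arrays 1, 2 and 3 at 0.921, 0.904 and 0.911. With KO arrays 2 and 3 it correlated at 0.904 and 0.822, so these correlations did not part KO array 1 from wild type. No more than 0.62% of values were identical between any 2 arrays.

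Elf5 itself was lower in all 3 KO arrays than in all 3 wild-type arrays. Its brighter probe set gave a signal of 9099 ± 2553 (SD, n = 3) in wild type and 4368 ± 1244 (SD, n = 3) in the KO, or 48.0% of wild type. A second probe set gave 7135 ± 2475 (SD, n = 3) and 2406 ± 1625 (SD, n = 3), or 33.7%. On the log2 scale the first Elf5 probe set differed by -1.06 ± 0.32 (SE), which did not pass over all genes (limma adjusted p = 0.109) and passed in the paired fit (adjusted p = 0.0151). Where these probe sets lie relative to the disrupted part of the gene is not given in the sources used here, so they do not show how much intact transcript was left.

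RNA quality differed between the arrays. The ratio of the 3' to the 5' control probe set of Gapdh, which is near 1 for full-length RNA, was 1.09, 0.833 and 0.876 in wild type and 0.802 in KO array 1, but 3.89 in KO array 2 and 13.6 in KO array 3. The Actb ratio was 1.20 to 2.04 in wild type, 1.58 and 1.87 in KO arrays 1 and 2, and 21 in KO array 3. The group difference of the log2 Gapdh ratio was 1.92 (exact permutation p = 0.4, two-sided). The first principal component of the genes tested held 58.0% of the variance. Wild-type arrays 1, 2 and 3 lay at -49.4, -34.4 and -21.0 on it, and KO arrays 1, 2 and 3 at -6.61, 31.9 and 79.6. The KO arrays thus followed the order of their Gapdh ratios, and the wild-type arrays did not. The 3 wild-type arrays and KO array 1 had a Gapdh ratio under 2, and values over these 4 arrays ("low-ratio arrays") are given beside each gene group that shifted or whose call they change. The bright end of the arrays differed as well. The highest signal of each array was 38413, 24229 and 13884 in wild type and 17018, 13035 and 12518 in the KO, a log2 difference of -0.74 (exact permutation p = 0.2, two-sided), and the Cre control, which is added to each hybridisation, read 27746, 19335 and 10208 in wild type and 11820, 12012 and 9854 in the KO (-0.66, exact permutation p = 0.3). The low-ratio arrays hold 1 KO array, which was assumed to vary like the wild-type arrays, so a list that passes there rests on KO array 1 alone and says nothing of the spread between KO mice.

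**Figure D1:**
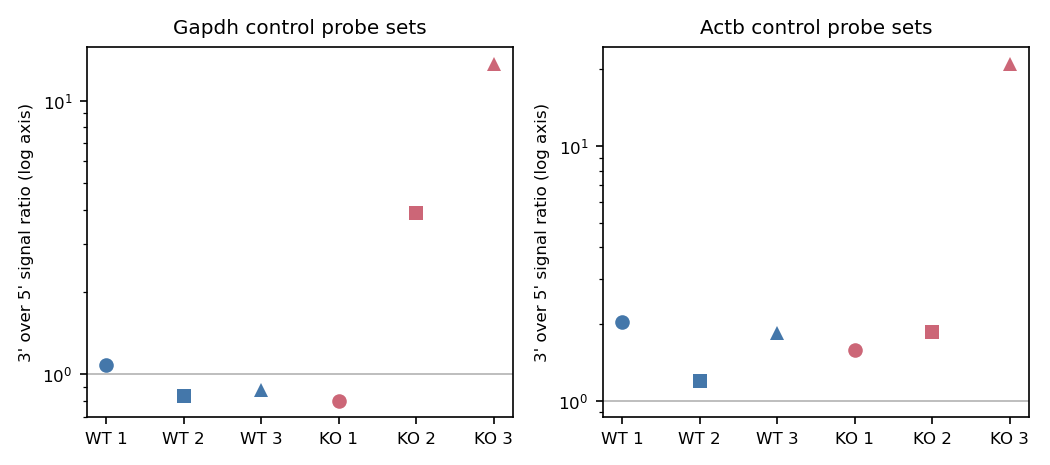
Ratio of the 3' to the 5' control probe set signal in each array on a log axis, for Gapdh (left) and Actb (right); wild type (WT) is blue, Elf5 KO red, circles, squares and triangles are replicate numbers 1, 2 and 3, and the grey line marks a ratio of 1. KO array 3 stood highest for both, at 13.6 and 21, and KO array 2 was raised for Gapdh at 3.89.

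The gland of Elf5 KO mice carried far more of several transcripts. Most of these were dim in wild type, but Inhbb read 144 to 284 there and Clic6 382 in wild-type array 1. Snorc, a cartilage proteoglycan, was higher by 4.39 ± 0.45 on the log2 scale (SE, adjusted p = 0.0124), and Atp6v1b1, a subunit of the proton-pumping V-type ATPase, by 3.35 ± 0.43 (adjusted p = 0.0229). Hey1, a transcriptional repressor induced by Notch, rose by 2.79 ± 0.28 (adjusted p = 0.0124) from signals of 51.8 to 70.4 in wild type to 423 to 564 in the KO. Prom1, a membrane protein of hormone-sensing luminal cells, rose by 2.94 ± 0.34. Clic6, a chloride channel family member, rose by 3.67 ± 0.62, the secreted pentraxin Ptx3 by 3.07 ± 0.40, the inhibin subunit Inhbb by 2.97 ± 0.38 (0.82 on a dimmer probe set), and Tph1, the rate-limiting enzyme of peripheral serotonin synthesis, by 2.63 ± 0.35. Adjusted p-values of these last 5 genes lay between 0.0229 and 0.0412.

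Fewer genes fell. Apln, which encodes the peptide hormone apelin, fell by 2.74 ± 0.53 on the log2 scale (SE, adjusted p = 0.0471), and Large2, a glycosyltransferase, fell by 2.38 ± 0.47. The transglutaminase Tgm1 fell by 2.35 ± 0.46 and Vstm5 fell by 1.97 ± 0.37. The tight junction protein Cldn8 fell by 1.89 ± 0.29 (adjusted p = 0.0356), from a mean of 11.29 ± 0.32 to 9.39 ± 0.14 (SD, n = 3). Fam160a2 fell by 1.86 ± 0.36, the multivitamin transporter Slc5a6 fell by 1.81 ± 0.30, and the ferroxidase Hephl1 fell by 1.81 ± 0.36. Adjusted p-values of the other 6 lay between 0.0356 and 0.0487, except for Hephl1. Hephl1 passed with an adjusted p that rounds to the threshold of 0.05. Cldn8 and Slc5a6 differed by -1.89 and -1.79 in the low-ratio arrays. The other falls shrank there, to -1.47 for Apln, -1.63 for Large2, -1.29 for Tgm1, -1.45 for Vstm5, -1.36 for Fam160a2 and -1.06 for Hephl1. Apln read 458, 161 and 76.1 in KO arrays 1, 2 and 3.

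**Figure D2:**
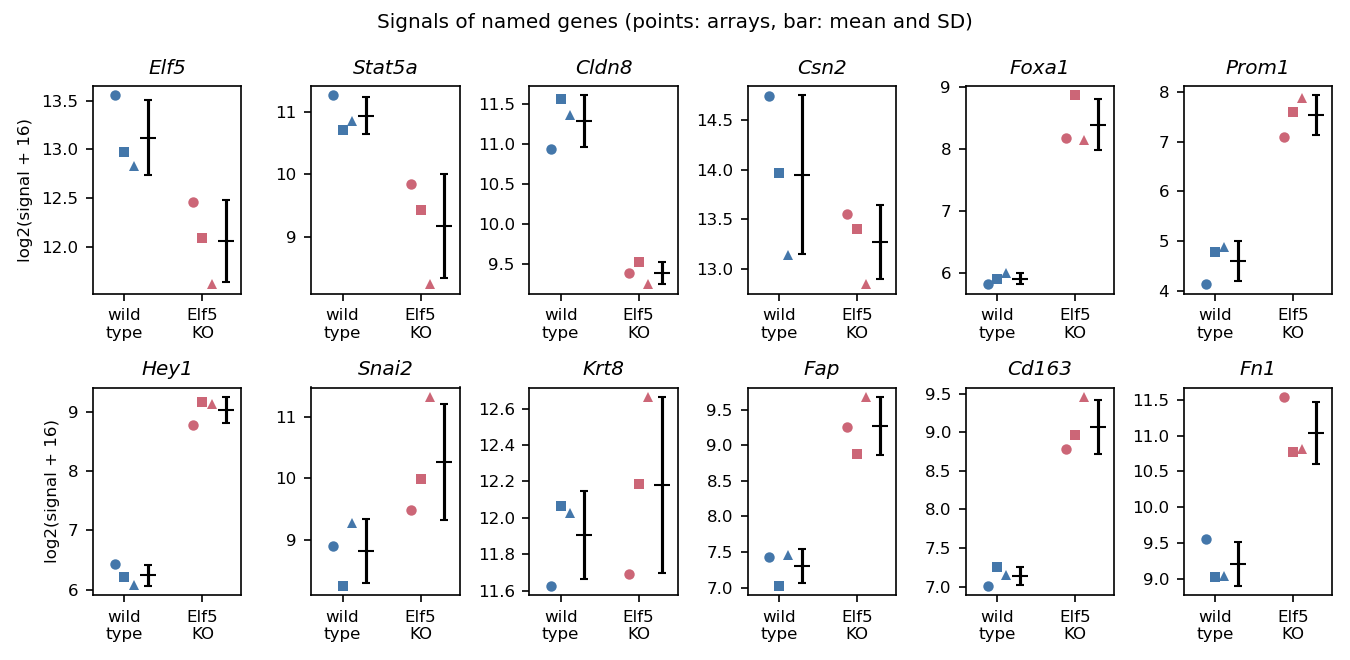
Log2(signal + 16) of 12 named genes in each array, with wild type in blue and Elf5 KO in red; circles, squares and triangles stand for replicate numbers 1, 2 and 3, and the black bars for the mean and SD of 3 arrays. Hey1 and Prom1 sat higher in all KO arrays and Cldn8 lower, while the groups overlapped for Csn2 and for Krt8, which was 0.27 higher in the KO on average and -0.21 with the 4 arrays of low Gapdh ratio alone.

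In all, 135 of 10916 genes changed: 123 rose and 12 fell. All 135 differed at least 2-fold, and in all 135 the 3 KO values lay on one side of the 3 wild-type values, as they did for 27.3% of all genes tested, where chance gives 10%. The paired fit called 1335 genes (841 higher, 494 lower, 1223 at least 2-fold), all 135 among them. The count rested on single arrays: limma called 9, 0 and 1 genes without wild-type array 1, 2 or 3, 1206 without KO array 1, and 1 and 6 without KO array 2 or 3, with 1656, 1553, 1910, 3481, 1803 and 1832 genes at an unadjusted p under 0.05, against 2384 with all arrays. Without KO array 1 only the KO arrays with Gapdh ratios of 3.89 and 13.6 remained, against at most 1.09 in wild type. There 653 genes rose and 553 fell, and genotype and RNA quality cannot be told apart. In the low-ratio arrays limma called 0 genes, with 1013 at an unadjusted p under 0.05. With 1 KO array left, the loss of calls in the low-ratio arrays does not show that the differences were absent. All 135 kept their direction there, which is fixed in advance where groups do not overlap. Of the calls 91.1% were higher, and 63.0% in the paired fit.

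Signals of milk proteins were lower in the KO arrays as a group, and so was the bright end of these arrays. All 16 measured members had a lower mean, with a median log2 difference of -0.92 (-0.41 in the low-ratio arrays). Xdh, a coat protein of the milk fat globule, differed by -1.77 ± 0.42, the lipid droplet protein Plin2 by -1.11 ± 0.29 and the bile-salt lipase Cel by -2.66 ± 0.81. Lalba, a subunit of lactose synthase, differed by -1.33 ± 0.65, the casein Csn2 by -0.68 ± 0.40 and the whey protein Wap by -0.51 ± 0.39. All 6 differences were smaller in the low-ratio arrays: Plin2 differed by -0.84 there, Cel by -0.42 and Lalba by -0.35. Csn2 differed by -0.40 and Wap by -0.32 there. Cel read 8586 in KO array 1, above wild-type array 3 (7914), and 1029 and 651 in KO arrays 2 and 3. Csn2 read 27414, 15974 and 9008 in wild-type arrays 1, 2 and 3, in the order of the Cre control and of the highest signal there. Csn2 and Wap lie near the top of the range and differed by about as much as these or less, so no change of their transcripts can be read from them. After quantile normalization, which gives all arrays 1 distribution, Csn2 differed by -0.14, Wap by -0.04, Lalba by -0.95, Xdh by -1.54, Plin2 by -0.77 and Cel by -2.41, and the list still passed downward (median -0.59, camera adjusted p = 0.000396). None of the 16 passed over all genes, 7 were lower adjusted over the list alone, and 11 fell in the paired fit, among them Xdh, Plin2, Cel and Lalba (adjusted p = 0.0121 to 0.0136), but not Csn2 (adjusted p = 0.0550) or Wap (adjusted p = 0.135). The list shifted downward (camera adjusted p = 7.25e-07; adjusted p = 0.356 with an estimated correlation).

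Lists for making and exporting milk components were also lower. In cholesterol synthesis 16 of 18 members had a lower mean, with a median of -0.86 (-0.37 in the low-ratio arrays). The enzymes Mvd, Sqle and Ebp differed by -1.12 ± 0.34, -1.11 ± 0.38 and -1.70 ± 0.58. Their differences were -0.52, -0.69 and -0.33 in the low-ratio arrays. In lactose synthesis and nutrient transport 16 of 21 were lower, with a median of -0.77 (-0.58 in the low-ratio arrays). There, the calcium pump Atp2b2 differed by -2.56 ± 0.68 and the nucleoside transporter Slc28a3 by -1.61 ± 0.42. The amino acid transporter Slc1a5 was higher by 1.80 ± 0.46. Atp2b2 differed by -0.91, Slc28a3 by -0.74 and Slc1a5 by 1.14 in the low-ratio arrays. None of the members of these lists passed over all genes. Adjusted over the list alone, 0 cholesterol genes passed, and 8 transport genes were lower and 1 higher. In the paired fit 5 cholesterol genes fell, and 8 transport genes fell and 2 rose, with all 6 named genes among those that passed. Both lists shifted downward, cholesterol synthesis with a camera adjusted p = 8.8e-05 (adjusted p = 0.252 with an estimated correlation) and transport with a camera adjusted p = 0.000334 (adjusted p = 0.252 with an estimated correlation).

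In the secretory pathway list 21 of 27 members had a lower mean, with a median of -0.44 (-0.24 in the low-ratio arrays). Xbp1 and Creb3l1, transcription factors of secretory capacity, differed by -0.81 ± 0.27 and -1.44 ± 0.44. Ssr4, a subunit of the translocon-associated complex, differed by -1.36 ± 0.37. Xbp1 differed by -0.53, Creb3l1 by -0.85 and Ssr4 by -0.72 in the low-ratio arrays. Other bright probe sets of Xbp1 differed by -1.94 and -1.67, and a much dimmer one of Ssr4 by -0.42. In milk lipid synthesis 21 of 26 were lower, with a median of -0.61. The fatty acid desaturase Fads1 differed by -1.15 ± 0.34 and the acyltransferase Gpat4 by -2.26 ± 0.72. By contrast Dgat2, which makes triglycerides, was higher by 1.64 ± 0.37 (0.70 on a dimmer probe set). Fads1 differed by -0.56, Gpat4 by -0.64 and Dgat2 by 2.33 in the low-ratio arrays. No member of these lists passed over all genes, and adjusted over the list alone 1 lipid gene was higher. With the paired fit 4 secretory genes fell, and 10 lipid genes fell and 2 rose, with all 6 named genes among them. Both lists shifted downward, secretory genes with a camera adjusted p = 0.00235 (adjusted p = 0.356 with an estimated correlation) and lipid genes with a camera adjusted p = 0.00107 (adjusted p = 0.520 with an estimated correlation). The milk lipid call was lost in the low-ratio arrays (median -0.18; camera adjusted p = 0.638, the highest of 23 settings, the lowest being 2.02e-09).

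Stat5a, which carries the prolactin signal to milk genes, was lower in all 3 KO arrays (-1.77 ± 0.42, adjusted p = 0.0662), and passed in the paired fit (0.0163). A second, dimmer Stat5a probe set differed by -2.95. Its homologue Stat5b differed by -0.49 ± 0.37, and by -1.47 on a dimmer probe set. The Stat5 target Cish differed by -1.54 ± 0.40 and the kinase Akt1 by -2.11 ± 0.53. Both fell in the paired fit (adjusted p = 0.0234 and 0.0169). Stat5a differed by -1.10 and Akt1 by -0.94 in the low-ratio arrays, against -1.63 for Cish and -0.51 for Stat5b. Akt1 read 1327, 607 and 236 in KO arrays 1, 2 and 3, and Stat5a 905, 676 and 288. The prolactin and Stat5 list as a whole did not shift (median 0.24, mean -0.12, camera adjusted p = 0.571, direction down). Of its 13 members 7 were higher and 6 lower, none passed over all genes, and 1 was higher and 4 lower adjusted over the list alone. In the paired fit 3 rose and 4 fell. Elf5, the disrupted gene, is itself a member and was 1 of the 4 in both counts. In 1 of 23 settings, the low-ratio arrays, the list passed downward (median -0.07), which rests on KO array 1. In the others camera adjusted p reached 0.931 with no call.

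Fibroblast and collagen transcripts were higher in the KO gland without exception: all 19 measured members had a higher mean, with a median log2 difference of 1.08. Fap, a serine protease of activated fibroblasts, rose by 1.96 ± 0.32 (SE, adjusted p = 0.0356), the matrix protein Dpt by 1.81 ± 0.34, the collagen Col5a2 by 1.65 ± 0.28 and the growth factor receptor Pdgfra by 1.79 ± 0.36. Pdgfra lies outside the rule for named genes and was chosen after its value was seen. These 4 passed over all genes, 9 adjusted over the list alone and 10 in the paired fit. The median difference was 1.16, 1.13 and 1.16 in replicate pairs 1, 2 and 3, and 1.31 in the low-ratio arrays. The list shifted upward (camera adjusted p = 2.76e-08; adjusted p = 0.201 with an estimated correlation). Endothelial genes did not shift (median 0.03, camera adjusted p = 0.489), although 1 of 16, the clotting factor carrier Vwf, rose by 1.54 ± 0.31. The phosphatase Ptprb was higher by 0.80 ± 0.29 (-0.03 on a somewhat dimmer probe set) and the transcription factor Sox17 by 0.74 ± 0.33 (0.04 on a dimmer one), without passing. The endothelial list passed upward in 3 of 23 settings: without KO array 3 (median 0.27, camera adjusted p = 0.0489), with the Gapdh ratio as a covariate (camera adjusted p = 0.0240) and in the low-ratio arrays (median 0.34, camera adjusted p = 0.0372), where it rests on KO array 1. The highest adjusted p was 0.863.

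Of 22 members of the epithelial-mesenchymal transition list, 18 had a higher mean (median 1.11, and 0.89 in the low-ratio arrays; camera adjusted p = 4.48e-05; adjusted p = 0.201 with an estimated correlation). Fibronectin, Fn1, rose by 1.83 ± 0.32 and the calcium-binding protein S100a4 by 1.98 ± 0.37, 13 members were higher adjusted over the list alone and 12 rose in the paired fit. A second, dimmer Fn1 probe set differed by -0.38. The protease Mmp3 was higher by 2.03 ± 0.43 (adjusted p = 0.0577, and 0.0195 in the paired fit). Snai2, a repressor of epithelial genes, was higher by 1.46 ± 0.48 (adjusted p = 0.133, and 0.0291 in the paired fit), and by 0.68 in the low-ratio arrays. Snai2 read 288 to 605 in wild type, and from 701 in KO array 1 to 2567 in KO array 3. The name of this Snai2 probe set marks possible cross-hybridisation, and a dimmer one differed by 0.92. Most of these genes are also expressed by fibroblasts.

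Genes of hormone-sensing luminal cells were higher on balance. Foxa1, a pioneer factor of the oestrogen receptor, rose by 2.47 ± 0.30 (SE, adjusted p = 0.0229) and Prom1 by 2.94 ± 0.34. The oestrogen-induced gene Greb1 differed by -0.99 ± 0.31 and fell in the paired fit, although a dimmer probe set differed by 0.99. Of 10 members 7 were higher (median 0.83, and 0.33 in the low-ratio arrays), 2 rose and 8 did not pass. Adjusted over the list alone 3 were higher and 1 lower, as in the paired fit. The list shifted upward (camera adjusted p = 0.0265; adjusted p = 0.252 with an estimated correlation), and lost its call in 2 of 22 settings, without KO array 2 (camera adjusted p = 0.0617, the highest, the lowest being 0.00115) and in the paired fit on replicates 1 and 3 (camera adjusted p = 0.0591).

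In the Notch list 18 of 23 members were higher (median 0.43, and 0.26 in the low-ratio arrays; camera adjusted p = 0.00859; adjusted p = 0.252 with an estimated correlation). Hey1 passed over all genes and 5 members adjusted over the list alone. In the paired fit 6 rose, Jag1 and Mfng among them. The ligand Jag1 was higher by 1.55 ± 0.37, the glycosyltransferase Mfng by 1.17 ± 0.30 and the receptor Notch1 by 0.72 ± 0.28 (adjusted p = 0.179), while dimmer probe sets of Jag1 differed by -0.59 and -0.57 and one of Notch1 by -0.25. The Notch call was lost when all probe sets of a gene were averaged (median 0.02, camera adjusted p = 0.450, the highest of 23 settings, the lowest being 0.000345). Luminal progenitor genes went both ways and did not shift (11 members, median -0.40, mean 0.21, camera adjusted p = 0.634, direction down). Of these Hey1 passed and 10 did not. Aldh1a3, a retinaldehyde dehydrogenase, was higher by 1.66 ± 0.56 and rose in the paired fit (adjusted p = 0.0191). Dimmer probe sets of Aldh1a3 differed by 0.10 and 0.07. In the paired fit 3 members of the list rose and 3 fell, the disrupted gene Elf5 among those that fell.

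Among general epithelial markers 17 of 24 were lower (median -0.45, and -0.38 in the low-ratio arrays; camera adjusted p = 0.0161; adjusted p = 0.252 with an estimated correlation). The tight junction gene Cldn1 went the other way and rose by 1.47 ± 0.28, although its dimmer probe sets differed by -0.20, 0.36 and 0.05. The adaptor Ap1m2 differed by -1.73 ± 0.49 and the protease inhibitor Spint1 by -0.96 ± 0.27, and both fell in the paired fit, where in all 7 members fell and 3 rose. Adjusted over the list alone 7 were lower and 2 higher. This call passed in 18 of 23 settings, with the lowest adjusted p in the low-ratio arrays, which rests on KO array 1. It was lost without wild-type array 3 (camera adjusted p = 0.0536), without KO array 1 (camera adjusted p = 0.0767, the highest), with no filter on dim genes (0.0728), with array weights (0.0604) and in the paired fit on replicates 1 and 2 (0.0519). The luminal keratin Krt8 differed by 0.27 ± 0.32. Basal and myoepithelial genes did not shift (21 members, median -0.24, camera adjusted p = 0.571). Krt5 differed by -0.24 ± 0.41 and Krt14 by 0.17 ± 0.61, and the sign of Krt5 turned without wild-type array 2 (0.0038) or KO array 1 (0.073), and that of Krt14 without wild-type array 1 (-0.40), KO array 2 (-0.08) or KO array 3 (-0.22). Egfr was higher by 1.70 ± 0.37 and the basal regulator Trp63 by 1.25 ± 0.41, and neither passed over all genes, while both rose in the paired fit (adjusted p = 0.0169 and 0.0486), where 3 members of the list rose and 0 fell. Dimmer probe sets of Trp63 differed by -0.24 to 0.48. The 7 probe sets of Egfr went both ways, and one brighter in wild type than the one used differed by -0.68. The basal list passed downward in 1 of 23 settings, the low-ratio arrays (camera adjusted p = 0.00216, against up to 0.985 elsewhere). That rests on KO array 1, with a median of -0.50 from the wild-type mean, while wild-type array 1 stood at -0.49 and KO array 2 at 0.48.

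Macrophage and myeloid markers were higher in the KO. Cd163 and Mrc1, scavenger receptors of tissue macrophages, rose by 1.93 ± 0.30 and 1.67 ± 0.29 (adjusted p = 0.0356 and 0.0446), and the Fc receptor Fcgr3 was higher by 1.19 ± 0.31 and rose in the paired fit, where 7 members rose and 0 fell. Of 17 members 14 were higher (median 0.90, and 1.33 in the low-ratio arrays; camera adjusted p = 0.00017; adjusted p = 0.252 with an estimated correlation), and 8 were higher adjusted over the list alone. All 10 B and plasma cell markers were higher and none passed over all genes (median 0.90, and 0.94 in the low-ratio arrays; camera adjusted p = 0.00168; adjusted p = 0.239 with an estimated correlation). The B cell genes Pou2af1, Ms4a1 and Cd79b were higher by 1.19 ± 0.34, 1.05 ± 0.31 and 1.01 ± 0.30. Adjusted over the list alone 3 members were higher, and 5 rose in the paired fit, these genes among them.

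T and NK cell markers did not shift (14 members, median 0.39, camera adjusted p = 0.191). Cd3d, a subunit of the T cell receptor complex, was higher by 1.94 ± 0.51, the interleukin receptor Il7r by 1.53 ± 0.45 and the surface protein Thy1 by 1.11 ± 0.28, none passing over all genes and all 3 rising in the paired fit, where in all 4 members rose and 1 fell. Thy1 is also a member of the fibroblast list. The list passed upward in 4 of 22 settings: without wild-type array 1 (camera adjusted p = 0.0382), without KO array 2 (camera adjusted p = 0.0484), with the mean of all probe sets (0.00771) and in the low-ratio arrays (median 0.62, camera adjusted p = 0.0118), where it rests on KO array 1. The highest adjusted p was 0.715. Antigen presentation did not shift (13 members, median 0.04, camera adjusted p = 0.571), although the class II genes H2-Ab1, Cd74 and H2-Eb1 were higher by 1.40 ± 0.32, 0.94 ± 0.33 and 0.92 ± 0.29 and rose in the paired fit, where 2 other members fell. Other probe sets of H2-Ab1 differed by 0.24, on one as bright in wild type as the one used, and by 0.48. In 1 of 23 settings, the low-ratio arrays, it passed upward (camera adjusted p = 0.0169, against up to 0.995 elsewhere). That rests on KO array 1, with a median of 0.33 from the wild-type mean, while wild-type array 1 stood at 0.36 and KO arrays 2 and 3 at -0.05 and -0.08.

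White adipocyte markers were higher for 13 of 15 members, none of them past the threshold (median 0.80, and 0.74 in the low-ratio arrays; camera adjusted p = 0.00108; adjusted p = 0.201 with an estimated correlation). The adipokine Retn was higher by 1.70 ± 0.48, the receptor Acvr1c by 1.99 ± 0.47 and the adipogenic factor Pparg by 1.23 ± 0.36. A second Acvr1c probe set, almost as bright in wild type, differed by 0.10, and a dimmer one by 0.96. Adjusted over the list alone 6 members were higher, and 6 rose in the paired fit, the named ones among them. Brown adipocyte markers did not shift (7 members, median 0.38, camera adjusted p = 0.956). Of these Cidea, also a lipid droplet protein of milk-secreting cells, differed by -2.34 ± 0.68, Otop1 by -1.20 ± 0.51 and Cox8b by 1.80 ± 0.80. In the paired fit Cidea and Otop1 fell and Cox8b rose. Cidea differed by -0.52, Otop1 by -0.16 and Cox8b by 2.28 in the low-ratio arrays. Cidea read 9236 in KO array 1, and 1219 and 1577 in KO arrays 2 and 3.

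Skeletal muscle markers were higher for all 15 members (median 1.39; camera adjusted p = 0.00107; adjusted p = 0.520 with an estimated correlation). They also differed between replicate numbers: Tnnc2, a troponin subunit, read 16.9, 392 and 57.0 in wild type and 427, 1311 and 488 in the KO. Another troponin subunit, Tnni2, was higher by 2.36 ± 0.81 and the myosin light chain Myl1 by 1.80 ± 0.63. Tnni2 and Myl1 overlapped between the groups. So did the list: the median of wild-type array 2 was 1.95 above the wild-type mean, against 1.06 and 0.86 in KO arrays 1 and 3. None of the muscle genes passed over all genes or adjusted over the list alone and 9 rose in the paired fit, these 3 among them. In the low-ratio arrays the call was lost (median 1.06, camera adjusted p = 0.0525, the highest of 23 settings, the lowest being 5.11e-11). Nerve and Schwann cell markers did not shift (5 members, median 0.82, camera adjusted p = 0.152), while the myelin protein Pmp22 rose by 1.60 ± 0.30. S100b was higher by 1.47 ± 0.41 and Sox10 differed by -1.09 ± 0.42, and both passed in the paired fit. Red cell and skin lists were too short to test. Of red cell genes, Alas2, an enzyme of haem synthesis, was higher by 1.31 ± 0.45 and rose in the paired fit, and Hbb-b2 differed by -0.08 ± 0.56 on its brighter probe set and by 1.52 on the other, and the sign of the first turned under median centring and without wild-type array 1 or 2 or KO array 2. Of skin genes, Casp14 differed by -0.55 ± 0.28, Krt10 by 0.46 ± 0.32 and Sbsn by -0.18 ± 0.32, the last with the sign turned under median centring and without wild-type array 3.

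**Figure D3:**
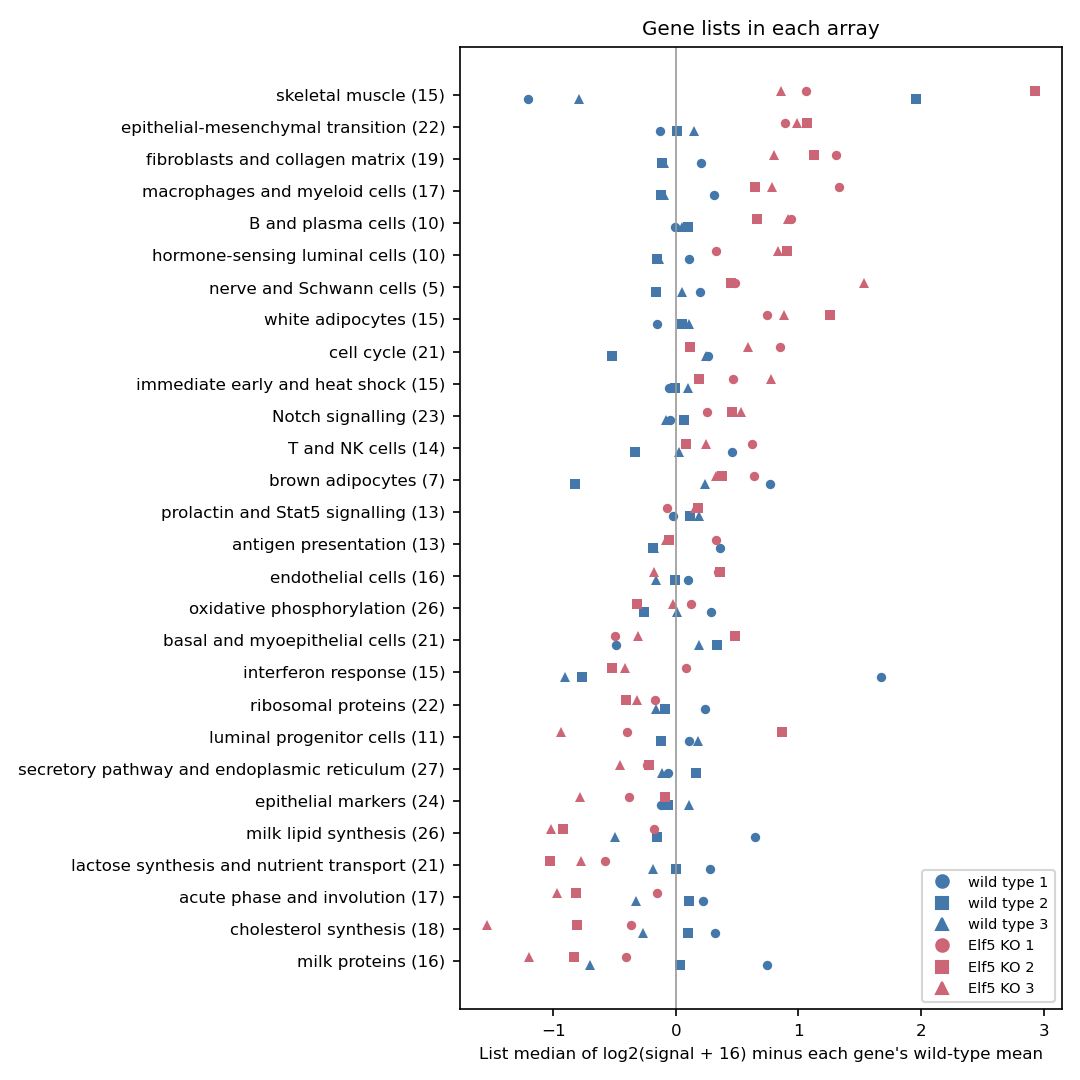
Median over the members of each gene list of log2(signal + 16) minus the gene's wild-type mean, 1 point per array, with the number of measured members in brackets; wild type is blue, Elf5 KO red, and circles, squares and triangles are replicate numbers 1, 2 and 3. The fibroblast list lay higher in every KO array than in any wild-type array, while for milk proteins wild-type array 3 overlapped the KO arrays.

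In the cell cycle list 15 of 21 members were higher (median 0.58, and 0.85 in the low-ratio arrays; camera adjusted p = 0.0317; adjusted p = 0.696 with an estimated correlation). Mcm3, Mcm5 and Mcm7, subunits of the replicative helicase, were higher by 1.36 ± 0.35, 1.75 ± 0.49 and 1.40 ± 0.41, none passing over all genes, and rose in the paired fit. The names of these 3 probe sets mark possible cross-hybridisation, and other probe sets differed by 0.21 to 1.13 for Mcm3, 0.42 and -0.23 for Mcm5, and 0.33 to 0.99 for Mcm7. The other 3 helicase subunits on the list differed by -0.14, 0.44 and 0.72 and passed in neither fit. Adjusted over the list alone 3 members were higher and 1 lower, as in the paired fit. The groups overlapped: the list median of KO array 2 was 0.12 above the wild-type mean, against 0.26 and 0.25 in wild-type arrays 1 and 3. The call passed in 17 of 23 settings, with the lowest adjusted p in the low-ratio arrays, which rests on KO array 1. It was lost without _s_at and _x_at probe sets (median 0.37, camera adjusted p = 0.273), without wild-type array 2 (0.495, the highest), without KO array 1 (0.355), with array weights (0.215), and in the paired fits on replicates 2 and 3 (0.0684) and on 1 and 3 (0.0652). In the acute phase and involution list 13 of 17 members were lower (median -0.83; camera adjusted p = 0.00239; adjusted p = 0.298 with an estimated correlation), with the chaperone Clu at -0.95 ± 0.26, which fell in the paired fit, and Saa3 at -1.34 ± 0.40, which did not. In the paired fit 5 members fell and 2 rose. Igfbp5, an insulin-like growth factor binding protein of the involuting gland, rose by 1.64 ± 0.29 on its brighter probe set, whose name marks possible cross-hybridisation, and differed by -1.02 on the other. The acute phase call was lost in 2 of 23 settings, in the low-ratio arrays (median -0.15, camera adjusted p = 0.269, the highest, the lowest being 0.000157) and with the Gapdh ratio as a covariate (0.0707).

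Ribosomal protein genes had a median of -0.30 (19 of 22 lower; camera adjusted p = 0.00791; adjusted p = 0.520 with an estimated correlation), and the median turned to 0.04 after quantile normalization, where the call was lost (camera adjusted p = 0.986). Rps14 differed by -0.67 ± 0.37, Rps2 by -0.62 ± 0.31 and Rpl14 by 1.49 ± 0.52, and in the paired fit Rps2 fell and Rpl14 rose. The ribosomal call passed in 15 of 23 settings, with 1.98e-05 the lowest adjusted p. It was also lost without wild-type array 1 (camera adjusted p = 0.0562), without KO array 2 (0.0534), in the low-ratio arrays (median -0.17, camera adjusted p = 0.0525), with no filter on dim genes (0.0752), with the mean of all probe sets (0.255), without _s_at and _x_at probe sets (0.115) and in the paired fit on replicates 2 and 3 (0.0599). Oxidative phosphorylation genes did not shift (26 members, median -0.09, camera adjusted p = 0.471), with Ndufb3 at 0.90 ± 0.33, Ndufa1 at -0.57 ± 0.29 and Cox4i1 at -0.50 ± 0.27. Immediate early and heat shock genes did not shift either (15 members, median 0.45, camera adjusted p = 0.113), although the transcription factor Egr1 rose by 1.57 ± 0.27. The heat shock genes Hspa1b and Hspb1 were higher by 0.95 ± 0.39 and 0.86 ± 0.31. That list passed upward in 5 of 23 settings: with no filter on dim genes (camera adjusted p = 0.0244), with a higher one (0.00914), with the mean of all probe sets (0.0367), with the Gapdh ratio as a covariate (0.0240) and in the low-ratio arrays (median 0.46, camera adjusted p = 0.0140), where it rests on KO array 1. The highest adjusted p was 0.521.

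The interferon list did not shift in the unpaired fit (15 members, median -0.26, camera adjusted p = 0.152) and did in the paired fit (camera adjusted p = 0.0497; adjusted p = 0.659 with an estimated correlation). The paired call rests on replicate pair 1, where the median difference was -1.49, against 0.25 and 0.29 in pairs 2 and 3. Wild-type array 1 stood apart: its list median was 1.67 above the wild-type mean, and all 3 KO arrays (0.09, -0.52 and -0.41) lay above wild-type arrays 2 and 3 (-0.76 and -0.90). Likewise Irf7, a regulator of interferon genes, read 1119 in wild-type array 1 against 242 and 124 in the other wild-type arrays. Irf7 differed by -1.21 ± 0.73 and Stat2 by -1.49 ± 0.47, both falling in the paired fit, and Ifit2 by 0.78 ± 0.50. The list passed downward in 5 of 23 settings, the others being without wild-type array 2 (camera adjusted p = 0.0071) or 3 (camera adjusted p = 0.00573) and the paired fits on replicates 1 and 3 (0.00442) and on 1 and 2 (0.000265). The highest adjusted p was 0.661.

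Of 28 lists, 17 shifted by camera at the preset correlation, 9 upward and 8 downward, and 18 in the paired fit. None passed with an estimated correlation, where the smallest adjusted p was 0.201, or 0.293 in the paired fit. By fry 10 lists moved on balance one way. The list of lactose synthesis and transport did so downward, and the fibroblast, epithelial-mesenchymal transition, hormone-sensing luminal, Notch, macrophage, B cell and white adipocyte lists upward, as did 2 lists that camera did not call, immediate early and heat shock (fry adjusted p = 0.0159) and nerve (fry adjusted p = 0.0441). The other 9 lists that camera called did not pass by fry: milk proteins (fry adjusted p = 0.182), milk lipid (0.388), cholesterol (0.106), secretory (0.155), epithelial markers (0.128), cell cycle (0.379), muscle (0.379), acute phase (0.173) and ribosomal proteins (0.182). In the paired fit 3 lists passed by fry: fibroblasts (0.00772), milk proteins (0.0347) and cholesterol (0.0347).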

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

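All tests in this part except the counts of splits were chosen after the result they bear on had been seen. Signals of control transcripts went above the highest wild-type array in several KO arrays. Of these the Gapdh ratio also served to pick the low-ratio arrays and as a covariate. The Gapdh 3' to 5' ratio was 3.89 in KO array 2 and 13.6 in KO array 3, against at most 1.09 in wild type. The Actb ratio was 21 in KO array 3, against 2.04. The transferrin receptor ratio was 5.11 and 36.8 in KO arrays 2 and 3, against 5.0, and the pyruvate carboxylase ratio 79.1 and 63.1, against 36.1; these last 2 ratios were added once they had been seen to be high. The SINE B1 repeat probe set read 4780 in KO array 1 and 7387 in KO array 3, against 3172.

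The first pattern is the set of gene differences between KO and wild type beside raised Gapdh ratios in 2 of 3 KO arrays. Such ratios are a sign of degraded RNA, although the Actb ratio of KO array 2 (1.87) lay within the wild-type range. If degradation were the whole cause, genes picked from replicates 2 and 3 would not differ between the arrays of replicate 1, which both had Gapdh ratios near 1. The 500 genes most clearly higher in the KO of replicates 2 and 3 (median 1.66) had a median of 1.07 in replicate 1 and 95.8% shared the direction, while random lists of like signal gave 0.04 to 0.15. For the 500 lower genes (median -1.63) it was -0.61 and 85.2%, against -0.00141 to 0.11. Both values lie outside the random ranges, but 1 KO array excludes nothing, so degradation stays open, and the smaller size in replicate 1 is also what a partial contribution would give.

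The second pattern is the higher level of fibroblast and other stromal genes. The test assumed that a smaller share of epithelial cells would raise all other cell types alike. Fibroblast genes exceeded endothelial ones by 1.04, with 0.74 to 1.13 over the 3 replicate pairs. The permutation p over 35 genes was 6e-05, genes not being independent. This argues against fewer epithelial cells as the whole cause only if that assumption holds, which was not tested. Endothelial genes had the lowest median of the cell types outside the epithelium (0.03, and 0.34 in the low-ratio arrays). Macrophage (0.90), B cell (0.90), nerve (0.82), white adipocyte (0.80) and muscle genes (1.39) lay near or above the fibroblast median of 1.08. T cell (0.39) and brown adipocyte genes (0.38) lay between. The gap thus rests on the lowest list, and a smaller share of epithelial cells stays open as part or all of the cause. In replicate 1 the fibroblast median was 1.16, against -0.31 to 0.24 for random lists, which again rests on 1 KO array. More fibroblasts, or more matrix transcripts per fibroblast, in the absence of Elf5 stays open and untested.

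Chance was examined by splitting the 6 arrays in other ways, which gives 10 splits, too few for a share under 0.05. The real split alone (1 of 10) reached its count each time: 135 genes changed against at most 1 in another split, 123 higher and 12 lower, each against at most 1 in either direction, and 135 at least 2-fold against 1. For lists shifted it was 17 against 4 to 13, so camera at the preset correlation called lists in every split. The other splits hold both genotypes on each side, so these counts are not a rate of false calls. With the replicate block 4 splits part all 3 pairs; the real one (1 of 4) called 1335 genes and the others at most 0, and 4 splits are again too few.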

How the results depend on the processing

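The low-ratio arrays, the Gapdh covariate and the paired fits on 2 replicate numbers were chosen after seeing the data. Counts below are genes changed, then higher, lower and at least 2-fold, against 135, 123, 12 and 135. They were 85, 81, 4 and 85 with a pseudocount of 1; 56, 53, 3 and 56 without a filter on dim genes; 291, 279, 12 and 291 with median centring; 2627, 1576, 1051 and 1586 with array weights; 75, 68, 7 and 75 with the mean of a gene's probe sets; and 46, 44, 2 and 46 without _s_at and _x_at probe sets. With quantile normalization 21 were lower. With the replicate block they were 1335, 841, 494 and 1223; with the block on replicates 2 and 3 1809, 961, 848 and 1792, on 1 and 3 19, 18, 1 and 19, and on 1 and 2 1680, 1064, 616 and 1251. All 4 counts were 0 by limma in the low-ratio arrays (1013 genes at an unadjusted p under 0.05), with the Gapdh covariate (1112) and when all 27022 probe sets were tested (4788). Leaving out 1 array gave 0 to 1206 changed, 0 to 653 higher, 0 to 553 lower and 0 to 1206 at least 2-fold. The highest of each came without KO array 1, which leaves only the KO arrays with raised Gapdh ratios. A threshold of 0.1 gave 728 genes, and treat against a fold of 1.5 gave 2. The median log2 difference of all genes was 0.06, and 0.28 with median centring, so changes under that setting are relative to another zero. The cause of these moves was not tested.

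Elf5 was lower in all 23 settings (-1.45 to -0.66, adjusted p = 0.00407 to 0.806; -1.26 to -0.84 with 1 array left out). It passed in 4: -0.92 with array weights (adjusted p = 0.0179), -1.06 with the replicate block (adjusted p = 0.0151), and with the block -1.04 on replicates 2 and 3 (adjusted p = 0.0122) and -0.99 on 1 and 2 (adjusted p = 0.00407). With an estimated correlation camera called 0 lists, and fry 10. Over the settings 13 of 28 lists kept their call, with 26 single losses, 20 gains and 0 reversals. A list counted as reversed only if it was called in the unpaired fit or in that setting. Uncalled lists could change direction, as oxidative phosphorylation did in the low-ratio arrays. Apart from the calls named beside each result, the replicate block changed no other call of a gene or list named here. The Gapdh ratio difference stayed above 0 without each array in turn (0.933 to 2.98).

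Among named genes, 1915 comparisons with another setting kept direction and call, 272 gained and 265 lost the call, and 24 reversed. Krt14 (0.17) was -0.29 with the mean of probe sets, -0.27 without _s_at and _x_at probe sets, -1.10 in the low-ratio arrays, -0.72 with the Gapdh covariate, and -0.40, -0.22 and -0.08 without wild-type array 1, KO array 3 and KO array 2 (-0.40 to 0.80 with each array left out). Krt8 (0.27) was -0.21 in the low-ratio arrays and -0.15 with the covariate, and Krt5 (-0.24) was 0.0038 and 0.073 without wild-type array 2 and KO array 1 (-0.57 to 0.073 with each array left out). Igfbp5 (1.64) was -1.02 without _s_at and _x_at probe sets, which leaves its other probe set. Hbb-b2 (-0.08) was 0.068 with a pseudocount of 1, 0.12 with quantile normalization, 0.14 with median centring, 0.55 in the low-ratio arrays, 0.30 with the covariate, 0.74 with the block on replicates 1 and 3, and 0.0073, 0.48 and 0.18 without wild-type array 1, wild-type array 2 and KO array 2. Sbsn (-0.18) was 0.042 with median centring, 0.046 without wild-type array 3 (-0.43 to 0.046 with each array left out) and 0.10 with the block on replicates 1 and 2. Apart from Igfbp5, the cause was not tested, and each of these genes differed by less than its spread. The dim filter, at a signal of 43.8, limits what can be said of faint transcripts.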

Other observations

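The genes and the list in this part were picked after values had been seen, while the limit for the list test was set before it was run. Single genes that rose in the KO included the dehydrogenases Aldh1a1, by 1.70 ± 0.34 (SE, limma adjusted p = 0.0498), and Adh1, by 1.96 ± 0.37, and the retinol carrier Rbp4, by 2.10 ± 0.32. So did Ppp1r3b and Ppp1r3c, which target a phosphatase to glycogen, by 2.32 ± 0.31 and 2.41 ± 0.43. Idh1, a cytosolic source of NADPH, rose by 2.49 ± 0.43. The neutrophil proteins S100a8 and S100a9 rose by 1.64 ± 0.30 and 1.80 ± 0.32, and the macrophage lectin Clec10a by 2.39 ± 0.35. Abca1, a cholesterol exporter, rose by 2.06 ± 0.27, with an SD of 0.14 in wild type and 0.06 in the KO (n = 3).

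Atp6v1b1 and Hepacam2 rose by 3.35 and 2.36, and Foxi1, the factor that drives acid-secreting cells in kidney and inner ear, was higher by 2.78 ± 0.61 (adjusted p = 0.0605, and 0.0132 in the paired fit). This trio led to the hypothesis that a wider programme of proton-secreting cells may be present. It was tested on 17 other genes of such cells, listed once the trio had been seen, of which 14 were on the array. Their median difference was -0.19, with 2 of 14 higher, and camera over all genes gave p = 0.0764, or 0.170 with an estimated correlation. By the limit set before the test, a p of 0.05 or more would speak against the programme, but 3 of the 14 genes lay above the filter on dim genes, and transcripts near background exclude nothing. Of those 3, Car2, the brightest, differed by -1.58 ± 0.44 and fell in the paired fit (adjusted p = 0.0125), Atp6v1c2 differed by -0.78 and Dmrt2 by 1.04, neither passing. Car2 went against the programme, and 3 genes that went both ways are too few to decide, so the hypothesis stays open.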
